A study of Homo sapiens with 10 samples.

How the data were processed

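Gene expression was measured on 10 Affymetrix arrays, each hybridised with biotin-labelled RNA from one culture sample of a mantle cell lymphoma cell line in logarithmic growth. There were 3 HBL2 PT, 3 HBL2 BR, 2 JEKO PT and 2 JEKO BR arrays. BR stands for the bortezomib-resistant cells and PT for the matched cells of the same line, which are taken here as the parental cells from knowledge of the study, since the labels give only the letters. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

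The values used are the deposited scores in a table of 54675 probe sets. MAS5 is named, without a version, per the submitters' processing notes, and the steps after it are not given in the sources used here. The deposited score was found to be the same set of values on every array, with the largest difference between sorted arrays equal to 0, a range of 0 to 4.99, a median of 0.73 and a 75th percentile of 1.18. Each score therefore depends only on the rank of a probe set on its array. The scale looks logarithmic, but its base is not stated, so changes are given as differences in deposited units and never as fold changes. A shift of most genes in one direction cannot be seen in such values. No detection calls were used here, and the number of arrays limits the precision.

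Of the probe sets, 62 were controls and 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none listed. Gene numbers of 41037 probe sets were found in the current RefSeq gene table, and 0 symbols needed an update. The table (assembly GRCh38.p14) was used only for names and for which genes neighbour each other. Probe sets with several symbols or none and control probe sets were left out. A probe set was kept if it lay at or above its array's 50th percentile on at least 2 arrays, and the one with the highest mean represented its gene, which left 14529 genes. All 10 arrays had a column, and 0 other columns of values were left aside.

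The scores were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with 4 group means in 1 fit. There were 6 residual degrees of freedom, and the mean prior degrees of freedom were 9.89. The contrasts were BR minus PT in each line, their mean, and the HBL2 change minus the JEKO change. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called changed. Values after ± are standard errors of that fit beside a change and standard deviations beside a mean. Overlaps of the lines, which share no arrays, were set against the product of their counts over the genes tested and tested with a two-sided Fisher's exact test, although genes are not independent.

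Of the choices, the groups, the fit, the filter, 25 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. An estimated correlation and fry were alternatives. A call lost with an estimated correlation does not by itself show that the members are correlated. In JEKO, p53 targets and T and NK cell markers lost theirs with estimates of -0.024 and -0.055, under the preset value. Named genes were the 10 largest rises and falls in each line among called genes whose BR and PT arrays did not overlap and whose mean reached the 50th percentile in a group, the 10 rises and 10 falls with the largest smaller change among genes called in both lines, the 5 largest differences each way between the lines, 22 genes set in advance, and up to 4 called members per list and line with the largest changes. Of the 22, 1 was not analysed here. Other called members of small lists are named where the list needs them, chosen after their values were seen. Genes of the immunoglobulin, HLA and histone families have close relatives that a probe set can also bind, which limits what their values show.

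Several points departed from the plan. The planned log2 step and its pseudocount of 16, with the alternatives 1 and 64, were written for linear intensities and were not applied to values already on a log-like scale. Quantile normalization and median centring were not run because all arrays already share 1 distribution. The planned count at a fold of at least 2 was replaced by a count at 0.3 units or more, a size chosen after the scale was seen. List tests were not repeated for some variance models or for fits of 1 line alone. Leaving out 1 JEKO array leaves a group of 1, which is then assumed to vary like the other groups.

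Alternatives set in advance were no filter, a 75th percentile filter, no trend, a robust trend, array weights, a fit of each line alone, a replicate block, the median over a gene's probe sets, no _x_at or _s_at probe sets, every probe set on its own, and each array left out in turn. Added after the data were seen were the percentile rank, the normal score of the rank, the beta-actin 5' minus 3' control value (a sign of RNA quality) as a covariate, and a fit without the 3 arrays where that value was lowest. Runs of neighbouring genes were sought with running medians of 41 genes against the highest window in 1000 shuffles of gene order. That search was made after a first look with window means had shown such runs. A first test of the runs, with called genes left out on the same arrays, was judged weak after its values had been seen, and a test on held-out arrays was then added. Both are given. The thresholds of these tests were set by judgement.

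The fit was tested on simulated data of 14529 genes. For HBL2 it recovered 50.7% of genes changed by 0.3 units, 80.6% at 0.5 and 100% at 1, with 3.75% of calls false. For JEKO the shares were 29.9%, 62.7% and 97.0%, with 3.82% of calls false. The simulation changed only 67, 67 and 66 genes at these sizes. It gave 160 calls in HBL2 and 131 in JEKO, against 1711 and 622 in the real data. The adjustment depends on how many genes change, so these shares do not carry over to the real comparisons. For HBL2, 10 of 10 simulated lists of 25 genes shifted by 0.2 were recovered, with 0 false calls among 90 lists. The simulated genes varied independently and the lists were random. This result therefore does not show how many false calls the list test gives for correlated genes. In the real lists the estimated correlation reached 0.48, for MHC class II. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.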

Results

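Messenger RNA levels were compared between bortezomib-resistant (BR) cells and matched PT cells of the mantle cell lymphoma lines HBL2 and JEKO. Mantle cell lymphoma is a tumour of mature B cells, and bortezomib is a drug that inhibits the proteasome. The series sets out to relate this resistance to plasma cell features, so genes of the plasma cell and B cell programs were read first. HBL2 had 3 PT and 3 BR arrays and JEKO had 2 of each. The correlation of arrays across probe sets was 0.931 to 0.958 within a group, 0.916 to 0.938 between HBL2 BR and PT, and 0.930 to 0.942 between JEKO BR and PT. Between the lines it was 0.891 to 0.912. The beta-actin 5' minus 3' control value, a sign of RNA quality, averaged -0.89 ± 0.34 (SD, n = 3) in HBL2 PT, -0.85 ± 0.17 (n = 3) in HBL2 BR, -0.76 ± 0.082 (n = 2) in JEKO PT and -0.88 ± 0.18 (n = 2) in JEKO BR. It was lowest on HBL2 PT replicate 1 (-1.25), HBL2 BR replicate 3 (-1.04) and JEKO BR replicate 2 (-1.01). The GAPDH 5' minus 3' control value was lowest on JEKO BR replicate 2 (-0.64), against -0.44 to -0.17 on the other arrays. It was not used in any fit, so statements on RNA quality below rest on beta-actin unless GAPDH is named.

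**Figure D1:**
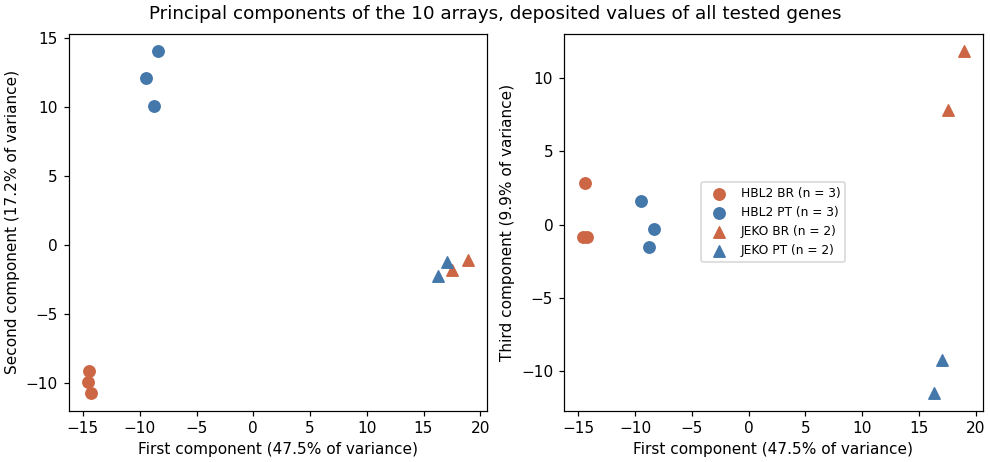
Principal components of the 10 arrays, computed from the deposited values of all tested genes. Each point is an array, circles are HBL2, triangles are JEKO, blue is PT and orange is BR. The first component (47.5% of variance) parts the lines, the second (17.2%) parts HBL2 BR from HBL2 PT, and the third (9.9%) parts JEKO BR from JEKO PT.

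In HBL2, several B cell surface and signalling genes were lower in BR cells. CD52, a lymphocyte surface glycoprotein, fell from 2.60 ± 0.15 (SD, n = 3) to 0.56 ± 0.22 (SD, n = 3), a change of -2.04 ± 0.11 (limma adjusted p = 6e-09). TCL1A, an AKT co-activator of B cells, fell by 1.94 ± 0.095 (adjusted p = 2.4e-09), and its neighbour TCL1B fell by 1.61 ± 0.079. CD180, a Toll-like receptor homologue of B cells, fell by 1.46 ± 0.074, and FCGR2B, the inhibitory Fc receptor, fell by 1.17 ± 0.098. CPXM1 (-1.38), AFF3 (-1.36), the class II gene HLA-DQA1 (-1.33) and the signalling adaptor TYROBP (-1.29) completed the largest falls with OSBPL10 (-1.43). The other 3 probe sets of OSBPL10 moved only between -0.31 and -0.018, and its call was lost with the median over its probe sets (adjusted p = 0.063) and without _x_at and _s_at probe sets (adjusted p = 0.75). That of HLA-DQA1 was lost with percentile ranks (adjusted p = 0.084). With the median over probe sets HLA-DQA1 fell by 0.36 and AFF3 by 0.30.

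Among the rises in HBL2 BR, the esterase gene BCHE went from 0.36 ± 0.30 to 1.96 ± 0.10 (SD, n = 3 each), a change of 1.60 ± 0.14 (adjusted p = 6.87e-07). OLFML2A rose by 1.504, the splicing regulator HNRNPLL by 1.40, the actin-binding protein gene CTTN by 1.23 and the sodium pump subunit ATP1B1 by 1.16. NLRP7, the LIM-homeobox gene LHX2, ADM, which encodes adrenomedullin, and the RAS-related RRAS2 each rose by 1.15, and ZNF462 rose by 1.07. CTTN rose by 0.58 with the median over probe sets, and HNRNPLL by 0.82 without _x_at and _s_at probe sets. In all, 1711 of 14529 genes changed in HBL2, 714 higher and 997 lower in BR, and 1026 of these changed by 0.3 units or more. Without HBL2 BR replicate 2 the count was 1118.

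The plasma cell list did not move one way in HBL2: 9 of 29 measured members rose and 7 fell (adjusted p = 0.47, camera), or 11 and 7 adjusted over the list alone. The members that rose included central regulators and surface markers of plasma cells. IRF4 rose by 0.43 ± 0.076 (adjusted p = 0.001), PRDM1, the gene of BLIMP1, by 0.38 ± 0.065 (adjusted p = 8.93e-04), CD38 by 0.36 ± 0.070 (adjusted p = 0.0022), and SDC1, which encodes CD138, by 0.39 ± 0.096 (adjusted p = 0.013). XBP1 rose by 0.21 ± 0.064 (adjusted p = 0.042), a call lost in 15 of the 23 alternatives run, including without any 1 array other than HBL2 PT replicate 3 (adjusted p = 0.055 to 0.19). The SDC1 call was lost without HBL2 BR replicate 3 (adjusted p = 0.069) and with percentile ranks in place of the deposited values (adjusted p = 0.36), as was that of CD38 with percentile ranks (adjusted p = 0.28). The elongation factor ELL2 (0.91) and caveolin CAV1 (0.86) rose most in the list, while the immunoglobulin joining chain JCHAIN (-1.08) and ITM2C (-0.76) fell. PRDM1 was no longer called with the median over its probe sets (0.18, adjusted p = 0.10) or with percentile ranks (adjusted p = 0.050).

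**Figure D2:**
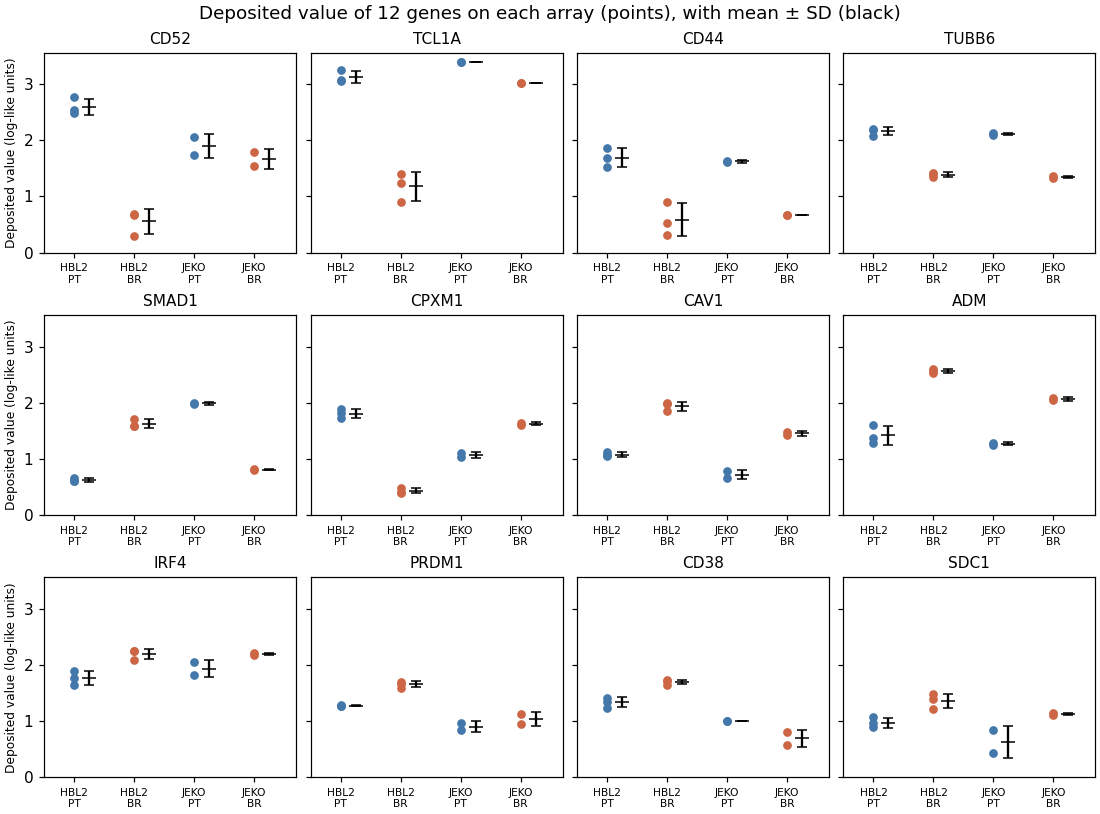
Deposited value of 12 genes on each array (vertical axis, log-like units; a panel per gene; blue PT, orange BR), with the mean and SD of each group in black. CD52 and TCL1A fall in HBL2 BR, CD44 and TUBB6 fall and CAV1 and ADM rise in BR of both lines, SMAD1 and CPXM1 move in opposite directions, and the 4 plasma cell genes in the bottom row move by less.

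Genes of the mature B cell program fell together in HBL2 BR, with 17 of 35 members lower, 1 higher and 17 not called, or 22 lower and 2 higher adjusted over the list alone. The list passed camera (adjusted p = 4.07e-14) but not with an estimated correlation (adjusted p = 0.069 with an estimated correlation). Beside TCL1A, the B cell coactivator POU2AF1 (-0.99), FCRLA (-0.94) and the kinase BLK (-0.91) fell, and FCER2, the low-affinity IgE receptor, was the member that rose (0.63). PAX5 changed by -0.18 ± 0.084 (adjusted p = 0.22) and MS4A1, the gene of CD20, by -0.18 ± 0.062 (adjusted p = 0.072). MS4A1 passed with array weights (adjusted p = 0.029) and with the beta-actin covariate (adjusted p = 0.033). B cell receptor signalling genes fell in 12 of 21 members and rose in 1, or 15 and 1 adjusted over the list alone (adjusted p = 2.29e-09; adjusted p = 0.11 with an estimated correlation). Its leading members were FCGR2B, PIK3CD (-0.52) and PRKCB (-0.45), against RASGRP3 (0.59). Of 8 measured myeloid markers, 3 fell (TYROBP, AIF1 and LYZ) and 0 rose, or 4 and 0 adjusted over the list alone (adjusted p = 7.39e-04; adjusted p = 0.11 with an estimated correlation). Of 12 immunoglobulin genes 0 were called, by either adjustment (adjusted p = 0.73).

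Antigen presentation genes fell in HBL2 BR as well. Of 13 MHC class II genes, 10 fell and 0 rose, or 11 and 0 adjusted over the list alone, with a median change of -0.63 (adjusted p = 4.07e-14; adjusted p = 0.078 with an estimated correlation). After HLA-DQA1 came HLA-DPA1 (-0.94), HLA-DRB1 (-0.94) and HLA-DPB1 (-0.82), and CIITA, the class II transactivator, changed by -0.11 ± 0.081 (adjusted p = 0.47). HLA probe sets can bind related HLA genes. In the immunoproteasome and antigen processing list 4 of 10 genes fell (PSMB8, PSMB9, B2M and TAP1) and 0 rose, the same counts as adjusted over the list alone (adjusted p = 0.0072; adjusted p = 0.32 with an estimated correlation). Interferon-stimulated genes fell in 9 of 28 members and rose in 1, or 11 and 1 adjusted over the list alone, led by OAS2 (-0.79), IRF7 (-0.44) and PARP9 (-0.44) against IFI44 (0.68). That list passed both tests (adjusted p = 1.54e-04; adjusted p = 0.046 with an estimated correlation).

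Cholesterol synthesis was the other list to pass both tests in HBL2 (adjusted p = 4.07e-14; adjusted p = 0.0036 with an estimated correlation). Of 18 members 15 fell and 0 rose, or 17 and 0 adjusted over the list alone, with a median change of -0.33. INSIG1, a sterol-regulated ER protein, fell by 0.71 ± 0.085, and the enzymes MSMO1 (-0.51), IDI1 (-0.50) and LSS (-0.50) followed. Adhesion and homing genes fell in 10 of 21 members and rose in 3, or 11 and 4 adjusted over the list alone (adjusted p = 9.17e-05; adjusted p = 0.069 with an estimated correlation). The hyaluronan receptor CD44 (-1.11), the oxysterol receptor GPR183 (-1.02), ITGB7 (-0.74) and ICAM3 (-0.72) led the falls.

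Proteasome subunits moved by small amounts in HBL2. In the 20S core, PSMB6 (0.35) and PSMA4 (0.33) rose and 0 of 13 genes fell, or 6 rose adjusted over the list alone (adjusted p = 4.08e-05; adjusted p = 0.078 with an estimated correlation). PSMB5, whose product bortezomib binds, changed by 0.073 ± 0.053 (adjusted p = 0.45). In the 19S regulator 3 of 19 genes rose (PSMC1, PSMD6 and PSMD11) and PSMD2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.005; adjusted p = 0.31 with an estimated correlation). ATF4 stress genes rose in 5 of 32 members, among them GARS1 (0.55) and ASNS (0.35), and fell in 0, or 8 and 1 adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.32 with an estimated correlation). The unfolded protein response list had 3 rises and 2 falls among 33 genes, or 9 and 2 adjusted over the list alone, and SEC61B (0.37) rose most. The falls were CRELD2, the largest called change of the list, and HERPUD1. The list passed camera (adjusted p = 0.049) but not fry (adjusted p = 0.11) or camera with an estimated correlation (adjusted p = 0.44). That call was lost without HBL2 PT replicate 1 (adjusted p = 0.057), HBL2 PT replicate 3 (0.22), HBL2 BR replicate 2 (0.11), HBL2 BR replicate 3 (0.055), JEKO BR replicate 1 (0.055) or JEKO BR replicate 2 (0.055).

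The other lists did not pass camera in HBL2. Heat shock genes had 1 rise and 1 fall of 19, or 1 and 2 adjusted over the list alone (adjusted p = 0.93), and HSPB1 fell by 0.66. NRF2 targets had 2 rises of 19, or 0 adjusted over the list alone (adjusted p = 0.25). In the BCL2 family BCL2A1 (-0.65), HRK (-0.40) and BCL2L2 (-0.30) fell and 0 of 14 rose, or 3 fell and 1 rose adjusted over the list alone (adjusted p = 0.099). With fry's test for change in 1 direction the BCL2 family passed downward (adjusted p = 8.55e-04), but camera with an estimated correlation did not pass it (adjusted p = 0.23). MCL1, BCL2 and PMAIP1, the gene of NOXA, changed by -0.14, -0.054 and 0.019, with adjusted p of 0.17, 0.66 and 0.93. NF-kB targets split into 6 rises, with NFKBIZ at 1.07, and 7 falls of 25, or 7 and 8 adjusted over the list alone (adjusted p = 0.92). Cell cycle genes had 2 rises and 1 fall of 36, or 0 and 1 adjusted over the list alone (adjusted p = 0.25). The p53 targets had 1 and 1 of 19 by both adjustments (adjusted p = 0.74), with CDKN1A, the gene of p21, falling by 0.37. Glycolysis and hypoxia genes had 2 rises and 4 falls of 24, or 2 and 7 adjusted over the list alone (adjusted p = 0.19). Autophagy and lysosome genes had 4 falls of 25, or 7 adjusted over the list alone (adjusted p = 0.24). T and NK cell markers (8 genes, adjusted p = 0.84), stromal and epithelial markers (8 genes, adjusted p = 0.94) and erythroid markers (5 genes, adjusted p = 0.24) had 0 called genes by either adjustment.

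In JEKO BR cells, MRFAP1L1, a gene of little known function, fell most, from 2.06 ± 0.035 to 0.54 ± 0.0089 (SD, n = 2 each), a change of -1.52 ± 0.087 (adjusted p = 1.23e-07). OXCT1, an enzyme of ketone body use, fell by 1.27 ± 0.14, and SMAD1, a transcription factor of BMP signalling, fell by 1.18 ± 0.075. KBTBD7 (-1.03), ARMCX6 (-1.02), YIPF6 (-1.001), CD44 (-0.95), SCRN1 (-0.90) and the histone gene H2BC12 (-0.79) followed. The call of KBTBD7 was lost without JEKO PT replicate 1 (adjusted p = 0.064) and without JEKO BR replicate 2 (adjusted p = 0.061). ARMCX6 had 1 other probe set, with a change of 0.21. With the median over probe sets ARMCX6 fell by 0.40 and YIPF6 by 0.57. The call of H2BC12 was lost with percentile ranks (adjusted p = 0.38) and that of SCRN1 with normal scores (adjusted p = 0.062). Percentile ranks leave bright genes little room to change, since the 98th percentile lay at 2.46. H2BC12 changed there by -1.73 points, while its deposited values went from 3.16 and 3.22 in PT to 2.34 and 2.45 in BR. The immunoglobulin gene IGKC fell by 0.99 on its brightest probe set, but the direction turned with the median over its probe sets (0.21, adjusted p = 0.32) and without _x_at and _s_at probe sets (2.42, adjusted p = 1.97e-10).

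The protease gene BACE2 rose most in JEKO BR, from 0.79 to 1.90, a change of 1.11 ± 0.099. LINC01088 (1.05), WDR86 (0.99), CFD, the gene of complement factor D (0.96), CT55 (0.93), the long noncoding RNA PURPL (0.92), IGFBP2 (0.92), TNFSF8 (0.90), the tyrosine kinase gene LCK (0.89) and PIGR (0.89) followed. With the median over probe sets the rises were 0.50 for LINC01088, 0.52 for TNFSF8 and 0.50 for PIGR, and without _x_at and _s_at probe sets that of BACE2 was 0.68. The other probe set of PIGR had a change of 0.12 (adjusted p = 0.76). With percentile ranks the calls of LCK (adjusted p = 0.27), IGFBP2 (0.27), TNFSF8 (0.18), PIGR (0.14) and LINC01088 (0.12) were lost. With normal scores those of IGFBP2 (adjusted p = 0.17), LINC01088 (0.14), WDR86 (0.096) and TNFSF8 (0.073) were lost. The call of IGFBP2 was lost without JEKO PT replicate 1 (0.58, adjusted p = 0.23) and without JEKO BR replicate 2 (adjusted p = 0.28), and that of LINC01088 without the latter (adjusted p = 0.070). In all, 622 genes changed in JEKO, 372 higher and 250 lower in BR, and 557 of these changed by 0.3 units or more. JEKO BR replicate 2 had the lowest beta-actin value in its line, and without it the count was 120. It was 208 without JEKO PT replicate 1, 246 without JEKO PT replicate 2, 281 without JEKO BR replicate 1 and 942 without HBL2 PT replicate 3, and it was 140 without the 3 arrays of lowest beta-actin value.

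The plasma cell list moved upward in JEKO BR, with 5 of 29 members higher and CD38 lower, or 10 and 4 adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.17 with an estimated correlation). CAV1 (0.74), the kinase PIM2 (0.71), FKBP11 (0.50), SDC1 (0.50) and LAX1 (0.37) rose. SDC1 varied in JEKO PT (0.63 ± 0.29, SD, n = 2), and its change was 0.29 without JEKO PT replicate 2 (adjusted p = 0.24). Its call was also lost without JEKO BR replicate 1 (adjusted p = 0.13), JEKO BR replicate 2 (adjusted p = 0.16) or _x_at and _s_at probe sets (0.26, adjusted p = 0.18). The fall of CD38 was at the threshold (-0.31 ± 0.085, adjusted p = 0.0495) and was lost in 12 of the 22 alternatives run, including without any 1 array other than HBL2 PT replicates 1 and 3 (adjusted p = 0.057 to 0.34). The change was -0.20 without JEKO BR replicate 1. IRF4 changed by 0.25 ± 0.093 (adjusted p = 0.15), PRDM1 by 0.14 ± 0.080 (adjusted p = 0.42) and XBP1 by 0.25 ± 0.078 (adjusted p = 0.086, or 0.034 without HBL2 PT replicate 3).

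B cell genes moved in both directions in JEKO. The mature B cell list had 3 rises (CXCR5, CD22 and BLNK) and 3 falls (TLR10, FCRL2 and BANK1) of 35, or 4 and 6 adjusted over the list alone. Its camera call (adjusted p = 0.044) was lost with an estimated correlation (adjusted p = 0.60 with an estimated correlation), without JEKO PT replicate 2 (adjusted p = 0.18) and without JEKO BR replicate 2 (adjusted p = 0.15). TLR10 fell by 0.48, and CXCR5, the receptor that guides B cells to follicles, rose by 0.39. PAX5 and MS4A1 changed by -0.014 and 0.096 (adjusted p = 0.97 and 0.58). The B cell receptor list had 3 rises, with NFATC1 at 0.45, and a fall of BTK (-0.34) among 21 genes, or 6 and 1 adjusted over the list alone (adjusted p = 0.092). With fry's test for change in either direction, the adjusted p was 1.02e-05 for the mature B cell and 3.29e-05 for the receptor list. That test is not particular to B cell genes. It also passed JEKO lists with 0 called genes, such as NRF2 (adjusted p = 1.64e-04) and the 19S regulator (adjusted p = 5.14e-04). With fry's test for change in 1 direction, the 2 B cell lists had adjusted p of 0.45 and 0.22. By camera the receptor list passed without JEKO PT replicate 2 (adjusted p = 0.039) or JEKO BR replicate 1 (adjusted p = 0.033). Immunoglobulin genes had a rise of IGLL5 (0.70) and the uncertain fall of IGKC among 12, or 4 and 1 adjusted over the list alone (adjusted p = 0.36), a list that passed with the median over probe sets (adjusted p = 0.007). Of 8 T and NK cell markers above the level filter, LCK, CD7 (0.62) and ZAP70 (0.45) rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.0036; adjusted p = 0.085 with an estimated correlation). The other 10 genes of that list were not tested. With percentile ranks the list did not pass (adjusted p = 0.14).

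Glycolysis and hypoxia genes rose in JEKO BR, with 7 of 24 higher and 0 lower, or 8 and 0 adjusted over the list alone (adjusted p = 6.44e-06; adjusted p = 0.21 with an estimated correlation). ADM (0.80), the aldolase ALDOC (0.56), the glucose transporter SLC2A3 (0.53) and PFKFB4 (0.46) led them. Interferon-stimulated genes rose in 4 of 28 members (IFIH1, IFI6, MX1 and IRF7) and fell in 0, or 7 and 0 adjusted over the list alone (adjusted p = 5.3e-04; adjusted p = 0.069 with an estimated correlation). The p53 targets CDKN1A (0.51), TP53INP1 (0.47) and MDM2 (0.28) rose and 0 of 19 fell, or 5 and 0 adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.076 with an estimated correlation). Cell cycle genes fell in 4 of 36 members (CENPE, CCNB2, TYMS and KIF11) and rose in 0, or 5 and 0 adjusted over the list alone (adjusted p = 5.3e-04; adjusted p = 0.069 with an estimated correlation). NF-kB targets rose in 8 of 25, among them CCR7 (0.55) and TNFAIP3 (0.52), and CD44 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.0087; adjusted p = 0.52 with an estimated correlation). That call was lost without JEKO PT replicate 1 (adjusted p = 0.15) and without JEKO BR replicate 1 (adjusted p = 0.084). Adhesion genes had 5 rises and 2 falls of 21, or 8 and 3 adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.22 with an estimated correlation), a call lost without JEKO PT replicate 2 (adjusted p = 0.071) or JEKO BR replicate 2 (adjusted p = 0.057). With percentile ranks the adhesion (adjusted p = 0.074) and NF-kB (0.063) calls were also lost.

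Proteasome genes had 0 calls in JEKO, among 13 genes of the 20S core (adjusted p = 0.75), 19 of the 19S regulator and 10 of the immunoproteasome list. Adjusted over the list alone these counts were 0, 2 falls and 2 rises. The 19S list passed camera downward (adjusted p = 0.044; adjusted p = 0.52 with an estimated correlation) and the immunoproteasome list upward (adjusted p = 0.015; adjusted p = 0.45 with an estimated correlation). The 19S call was lost without JEKO PT replicate 1 (adjusted p = 0.48), JEKO BR replicate 2 (adjusted p = 0.38) or HBL2 PT replicate 2 (adjusted p = 0.050), and the immunoproteasome call without JEKO PT replicate 2 (adjusted p = 0.086) or JEKO BR replicate 2 (adjusted p = 0.057). PSMB5 changed by -0.012 ± 0.065 (adjusted p = 0.96).

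Stress and survival genes gave few calls in JEKO. ATF4 targets rose in 3 of 32 (ATF5, DDIT4 and ATF3), or 4 adjusted over the list alone, and 0 fell (adjusted p = 0.083). That list passed without JEKO PT replicate 2 (adjusted p = 0.043) or JEKO BR replicate 1 (adjusted p = 0.011). In the BCL2 family BIK (0.52) and BCL2 (0.43) rose and 0 of 14 fell (adjusted p = 0.14, camera). Adjusted over the list alone, 2 rose and 1 fell. With fry's test for change in 1 direction the family passed upward (adjusted p = 0.0027), but camera with an estimated correlation did not pass it (adjusted p = 0.35). The BCL2 call was lost without JEKO BR replicate 2 (adjusted p = 0.074) and with the median over its probe sets (0.19, adjusted p = 0.19). Heat shock genes had a rise of DNAJB6 among 19, or 1 rise and 3 falls adjusted over the list alone (adjusted p = 0.083), and passed without HBL2 PT replicate 3 (adjusted p = 0.045), JEKO PT replicate 2 (adjusted p = 0.0069) or JEKO BR replicate 1 (adjusted p = 0.0097). Stromal and epithelial markers had a fall of VIM (-0.35) among 8 by both adjustments (adjusted p = 0.45). By either adjustment, limma called 0 genes of the unfolded protein response (33 genes, adjusted p = 0.16, or 0.041 without JEKO PT replicate 1), NRF2 (19 genes, adjusted p = 0.88), MHC class II (13 genes, adjusted p = 0.92), cholesterol synthesis (18 genes, adjusted p = 0.83), autophagy and lysosome (25 genes, adjusted p = 0.97), myeloid (8 genes, adjusted p = 0.75) and erythroid (5 genes, adjusted p = 0.69) lists.

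**Figure D3:**
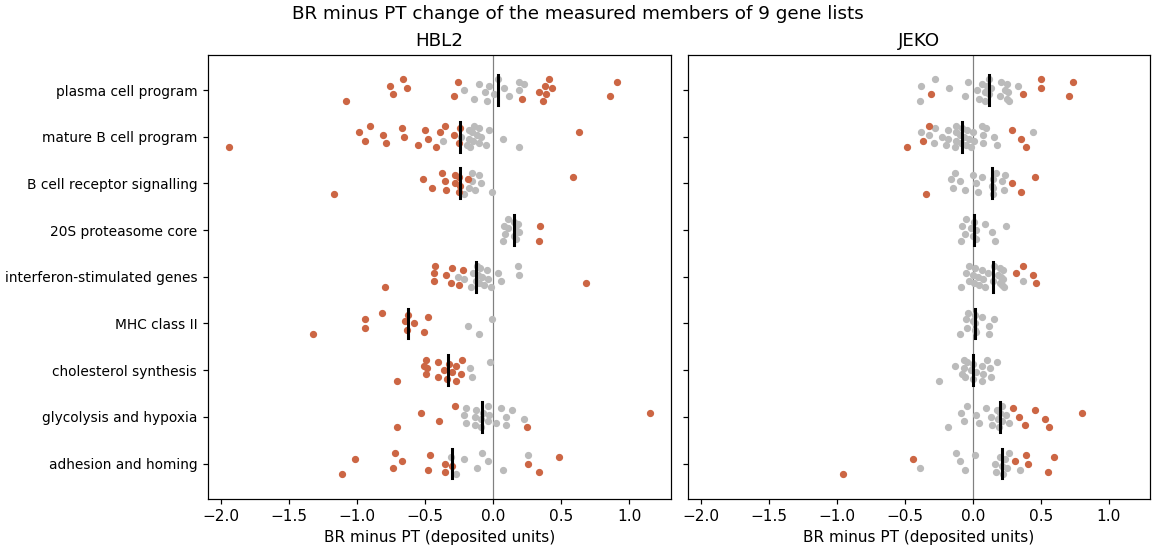
BR minus PT change in deposited units (horizontal axis) of each measured member of 9 gene lists in HBL2 (left) and JEKO (right); orange points passed the gene test, grey points did not, and black bars are list medians. The MHC class II median is -0.63 in HBL2 and 0.013 in JEKO, and the cholesterol synthesis median is -0.33 in HBL2 and 0.0015 in JEKO.

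A set of genes moved the same way in both lines. CD44 fell by 1.11 ± 0.11 in HBL2 and by 0.95 ± 0.14 in JEKO, and the tubulin gene TUBB6 fell by 0.77 ± 0.058 and by 0.77 ± 0.071. The JEKO call of CD44 was lost with percentile ranks (adjusted p = 0.11) and normal scores (adjusted p = 0.064). With the median over its probe sets CD44 fell by 0.42 in HBL2 and by 0.43 in JEKO. TCL1B fell by 1.61 and by 0.59, the latter call being lost without JEKO BR replicate 2 (adjusted p = 0.054) and with percentile ranks (adjusted p = 0.93). SH3BP4 fell by 0.52 and by 0.59. MIR146A, the host of a microRNA induced by NF-kB, rose by 0.83 ± 0.072 in HBL2 and by 0.83 ± 0.088 in JEKO. ADM rose by 1.15 and 0.80, CAV1 by 0.86 and 0.74, NLRP7 by 1.15 and 0.69, the ATP receptor gene P2RX5 by 0.66 and 0.67, and WNT10A by 0.57 and 0.59. The JEKO call of P2RX5 was lost with percentile ranks (adjusted p = 0.17). That scale leaves bright genes little room to change. The JEKO changes on it were 2.19 points for P2RX5 and -1.60 points for TCL1B.

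Several of the other genes named for both lines were less stable in JEKO. PURPL rose by 0.56 in HBL2 and 0.92 in JEKO, and FAM107B fell by 0.58 and by 0.42. DNAJC6 rose by 0.94 and 0.56, with the JEKO call lost without JEKO PT replicate 2 (0.36, adjusted p = 0.20) or JEKO BR replicate 2 (0.23). LHX2 rose by 1.15 and 0.50, with the JEKO call lost without JEKO PT replicate 1 (adjusted p = 0.20), JEKO BR replicate 1 (0.079) or JEKO BR replicate 2 (0.16). SMIM14 fell by 0.59 and by 0.48 and JAML, a junctional adhesion molecule, by 0.46 and by 0.52. Their JEKO calls were lost without any 1 JEKO array, with adjusted p of 0.066 to 0.22 and of 0.064 to 0.13. PECAM1, the gene of CD31, fell by 0.47 and by 0.44, with the JEKO call lost without JEKO PT replicate 1 (-0.25, adjusted p = 0.30), JEKO BR replicate 1 (0.12) or JEKO BR replicate 2 (0.16). PPM1K fell by 0.42 and by 0.44, with the JEKO call lost without JEKO PT replicate 2 (adjusted p = 0.092) or JEKO BR replicate 1 (0.088) and the HBL2 call with the median over its probe sets (-0.16, adjusted p = 0.084), where the JEKO change was -0.27. OSBPL10 fell by 1.43 and by 0.58 and EPB41L4B rose by 0.51 and 0.59. Without _x_at and _s_at probe sets the calls of OSBPL10 (adjusted p = 0.75 and 0.53) and EPB41L4B (0.92 and 0.47) were lost in both lines.

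In total 91 genes changed in the same direction in both lines, 55 higher in BR against 18.3 for independent lists (Fisher's exact p = 1.78e-13) and 36 lower against 17.2 (p = 2.14e-05). A further 69 were lower in HBL2 BR and higher in JEKO BR against 25.5 (Fisher's exact p = 1.91e-14), and 18 were higher in HBL2 and lower in JEKO against 12.3 (p = 0.10). Benjamini-Hochberg adjusted values of these 4 tests were 3.55e-13, 2.86e-05, 7.64e-14 and 0.10. Across all genes, which are not independent replicates, the changes had a Pearson r of -0.0091 and a Spearman rho of -0.020. The count of 91 depended on single arrays, being 24 without JEKO BR replicate 2, 38 without JEKO PT replicate 1, 41 without JEKO PT replicate 2 or JEKO BR replicate 1, and 58 without HBL2 BR replicate 2, and it was 23 without the 3 arrays of lowest beta-actin value.

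**Figure D4:**
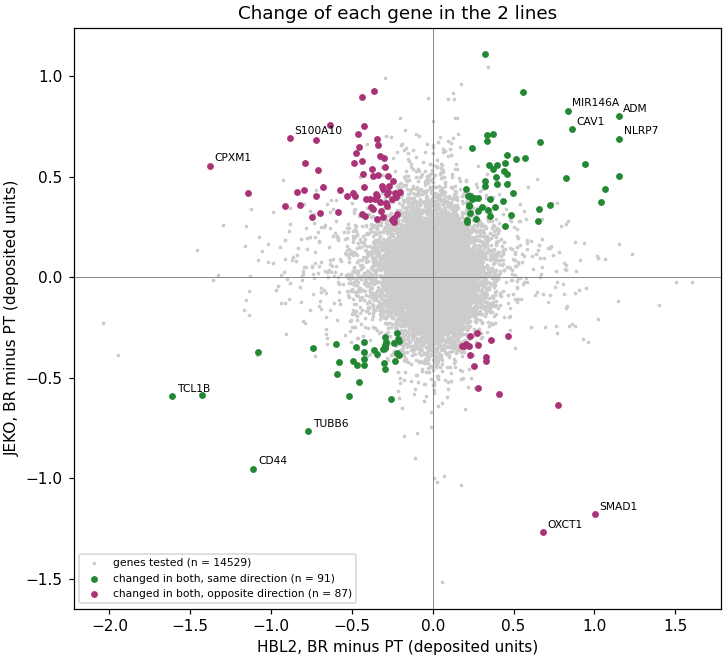
BR minus PT change of each of the 14529 genes in HBL2 (horizontal axis) and JEKO (vertical axis), in deposited units; green points are the 91 genes called in both lines in the same direction and purple points the 87 called in opposite directions. CD44, TUBB6 and TCL1B lie low in both lines, and SMAD1 and OXCT1 lie high in HBL2 and low in JEKO.

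The mean change over the lines was called for 1130 genes, 549 higher and 581 lower in BR. CAV1 rose by 0.80 ± 0.050, ADM by 0.98 ± 0.057, SDC1 by 0.44 ± 0.076 (adjusted p = 0.0015), IRF4 by 0.34 ± 0.060 (adjusted p = 0.0019) and PRDM1 by 0.26 ± 0.052 (adjusted p = 0.0053). The plasma cell list rose in 9 and fell in 5 of 29 members (adjusted p = 0.025; adjusted p = 0.25 with an estimated correlation), a call lost without HBL2 BR replicate 3 (adjusted p = 0.052) or JEKO BR replicate 2 (adjusted p = 0.057). The mature B cell list fell in 18 and rose in 2 of 35 (adjusted p = 1.34e-11; adjusted p = 0.19 with an estimated correlation), and the cholesterol synthesis list fell in 8 of 18 (adjusted p = 1.73e-09; adjusted p = 0.012 with an estimated correlation). A changed mean can come from 1 line. The cholesterol synthesis median was -0.33 in HBL2 and 0.0015 in JEKO, and the mature B cell median was -0.25 and -0.080. In JEKO, IRF4 and PRDM1 were not called by limma (adjusted p = 0.15 and 0.42). The count of 1130 was 617 without JEKO BR replicate 2, 667 without JEKO PT replicate 2, 668 without JEKO BR replicate 1 and 685 without JEKO PT replicate 1, and it was 572 without the 3 arrays of lowest beta-actin value.

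Of the genes set in advance, limma did not call PAX5, MS4A1, PSMB5, PMAIP1, MCL1 and CIITA in either line. The others not called in either line were CCND1, the cyclin D1 gene of mantle cell lymphoma (-0.014 in HBL2 and -0.25 in JEKO, adjusted p = 0.93 and 0.085), SOX11 (0.062 and -0.13), BCL6 (0.068 and 0.074), the chaperone gene HSPA5 (0.029 and -0.016), DDIT3 (0.088 and 0.23), TNFRSF17, the gene of BCMA (0.0068 and 0.065), CD27 (-0.14 and -0.18), MYC (0.19 and 0.079) and the drug efflux pump gene ABCB1 (-0.059 and -0.15). For these others, from CCND1 to ABCB1, the adjusted p ranged from 0.076 for MYC in HBL2 upward. CCND1 in JEKO passed with that line fitted alone (adjusted p = 0.023), with array weights (0.040) and with the beta-actin covariate (0.025). MYC passed in HBL2 with array weights (adjusted p = 0.0077), with the beta-actin covariate (0.025), and without HBL2 PT replicate 3 (adjusted p = 0.035) or HBL2 BR replicate 3 (adjusted p = 0.025). JEKO changes of PMAIP1 (-0.072) and MCL1 (0.10) had adjusted p of 0.82 and 0.52, and CIITA changed there by -0.053 (adjusted p = 0.85).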

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

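The results here were singled out because the BR versus PT change differed between HBL2 and JEKO in a test of the difference itself (HBL2 change minus JEKO change, limma, adjusted p under 0.05). No group had the 4 arrays that the test used for single outlying values needs. Of the tests below, the splits of the arrays were planned before the data were seen.

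The change differed between the lines for 1266 of 14529 genes. The HBL2 change minus the JEKO change was positive for 429 and negative for 837 of them. That count was 696 without JEKO PT replicate 1, 832 without JEKO PT replicate 2 and 658 without JEKO BR replicate 2, and it was 619 without the 3 arrays of lowest beta-actin value. SMAD1, a BMP signalling factor, rose by 1.004 in HBL2 and fell by 1.18 in JEKO, a difference of 2.18 ± 0.096 (adjusted p = 2.32e-09). OXCT1 differed by 1.95 ± 0.18, BCHE by 1.63 ± 0.21, MRFAP1L1 by 1.58 ± 0.11 and HNRNPLL by 1.54 ± 0.17. CPXM1 fell in HBL2 and rose in JEKO, a difference of -1.93 ± 0.10 (adjusted p = 1.35e-08). The other large negative differences were CD52 (-1.81 ± 0.17), CD180 (-1.59 ± 0.12), S100A10 (-1.58 ± 0.12) and TCL1A (-1.56 ± 0.15). With the median over probe sets S100A10 changed by -0.56 in HBL2, with 0.33 in JEKO (adjusted p = 0.076). With percentile ranks the call of CPXM1 in JEKO (adjusted p = 0.053) and that of OXCT1 in HBL2 (adjusted p = 0.28) were lost. Among genes set in advance, CD38 differed by 0.68 ± 0.11 (adjusted p = 0.0011) and BCL2 by -0.48 ± 0.095 (adjusted p = 0.0045). Of 44 other named genes, 27 also differed.

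Of 25 lists, 15 differed by camera, and 2 of them also with an estimated correlation. These were the interferon-stimulated genes (median difference -0.29, adjusted p = 2.69e-07; adjusted p = 0.010 with an estimated correlation) and cholesterol synthesis (-0.31, adjusted p = 3.2e-08; adjusted p = 0.010 with an estimated correlation). The other median differences were -0.27 for mature B cell, -0.32 for B cell receptor, 0.091 for 20S, 0.13 for 19S and -0.30 for immunoproteasome genes, with adjusted p of 0.13, 0.11, 0.14, 0.14 and 0.14 with an estimated correlation. They were -0.22 for the BCL2 family, 0.098 for cell cycle, -0.20 for p53 and -0.65 for MHC class II genes, with 0.11, 0.059, 0.11 and 0.11 with an estimated correlation. They were -0.20 for glycolysis, -0.36 for adhesion, -0.40 for T and NK cell and -0.45 for myeloid genes, with 0.16, 0.059, 0.11 and 0.13 with an estimated correlation.

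Splits of the arrays into other groups were fitted in the same way. Of 10 splits of the HBL2 arrays, 1 reached the real count of 1711, the real one itself, and the highest other count was 0, but 10 splits are too few to reach 0.05. Of 60 splits for the mean over the lines, 2 reached the real count of 1130. The other 1 gave 1266 and is the split that keeps the true groups but exchanges JEKO PT and BR, and the next highest count was 318.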

How the results depend on the processing

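The alternatives that rank values, use the beta-actin value or leave out 3 arrays were chosen after seeing the data. Of the counts under alternatives, 86 stayed within 1.5 times and 32 did not. Of the list results, 1842 kept their side of the threshold, 112 lost a call and 38 gained one. Of the named gene results, 2660 kept it, 128 lost a call, 14 gained one and 2 reversed, and 50 of 89 called changes kept their call under every alternative. The cause was not tested except where fewer arrays or genes enter a fit.

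For JEKO (622), the same direction in both lines (91), HBL2 (1711), the mean (1130) and the difference (1266), array weights gave 1032, 169, 2684, 1738 and 1948. Without an intensity trend JEKO had 389 and both lines 50. Both lines had 56 without _x_at and _s_at probe sets, 43 with percentile ranks and 48 with normal scores. Without the 3 arrays of lowest beta-actin value JEKO had 140, the mean 572, the difference 619 and both lines 23. Leaving out each array gave 1118 to 1647 for HBL2, 120 to 942 for JEKO, 617 to 1301 for the mean, 658 to 1473 for the difference and 24 to 121 for both lines.

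With an estimated correlation the adjusted p was 0.069 for mature B cell genes in HBL2, 0.17 for plasma cell genes in JEKO and 0.60 for mature B cell genes in JEKO. The last was also 0.45 with fry, 0.060 with the 75th percentile filter, 0.27 with the median over probe sets, 0.092 with percentile ranks, 0.058 with normal scores and 0.16 without the 3 arrays. Leaving out each array gave it 0.024 to 0.18, and 0.0017 to 0.013 for plasma cell genes in JEKO. In HBL2 the ranges were 5.23e-16 to 3.1e-13 for mature B cell and 0.38 to 0.73 for plasma cell genes. IGKC in JEKO reversed to 0.21 with the median over probe sets and to 2.42 without _x_at and _s_at probe sets.

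Replicate numbers did not pair the arrays. Same-numbered residuals correlated at 0.017, 0.14 and 0.0075 in HBL2 and 0.078 in JEKO, and in HBL2 only replicate 2 correlated best with its own number. With a replicate block the counts were 1741 for HBL2, 601 for JEKO, 1086 for the mean, 1257 for the difference and 98 for both lines. Pseudocounts, quantile normalization and median centring were not run. Without detection calls, the level at which signal meets background could not be set.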

Other observations

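The tests of copy number and of the overlap were planned before their values were seen. The tests of RNA quality, of a few strong genes and of JEKO BR replicate 2 were chosen only after the result was seen.

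Histone genes of the replication type were looked at after their values were seen. In JEKO BR 9 of 36 fell and 0 rose, with a median change of -0.27, and in HBL2 BR 4 fell and 0 rose, with a median of -0.041. H2BC12 (-0.79), H1-2 (-0.67), H2BC21 (-0.61) and H2BC6 (-0.60) fell most in JEKO. Of the 36, 34 lie in the run of neighbouring genes from H3C2 to OR2B6 that shifted together in JEKO (51 genes, median -0.185). Of these 34, 8 fell (median -0.27), and they are the 8 genes called lower in that run. Most of the run is thus the family itself, and none of its other genes was called. The run therefore does not show a change of the region apart from the family. Of the 2 histone genes outside it, 1 fell (H2BC21). Their sequences are alike, so a probe set can bind several of them.

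Neighbouring genes shifted together in 10 runs with 799 of 14488 placed genes in HBL2 and in 12 runs with 816 genes in JEKO. In HBL2 the run from LOC100288570 to TTN-AS1 had 187 genes with a median of -0.17, and the run from RPH3AL to SPEM1 had 119 with a median of 0.18. The run from C2 to ITPR3 holds MHC class II genes. In JEKO the run from INPPL1 to ZBTB16 had 174 genes with a median of -0.17, and that from ZNF282 to VIPR2 had 72 with a median of 0.16.

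A hypothesis is that these runs could come from DNA copy number, which the values here do not decide. In runs found on part of the arrays, 70.9% of genes in HBL2 and 73.6% in JEKO shifted the same way on the held-out arrays, but any real difference between BR and PT cells would repeat there. With the beta-actin covariate 101% and 98.3% of the shift was left, but that value hardly differed between the groups, so RNA quality stays open. A first test of a few strong genes left out called genes on the arrays that chose the runs, and its medians of 0.075 and 0.13 decide nothing, so a test on held-out arrays was added after those values were seen. The held-out test used 1 held-out BR and 1 PT array per line. Uncalled run genes shifted there by 0.0283 in HBL2 (55.4% the same way) and by 0.104 in JEKO (68.8%). Over all run genes the shares were 70.9% in HBL2 and 73.6% in JEKO, against 67.6% and 58.0% if called genes alone had moved. Genes were called in the fit of all arrays, the held-out ones included, and which genes are called depends on power. A few strong genes, copy number and regional chromatin therefore stay open in both lines.

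Leaving out JEKO BR replicate 2 lowered the JEKO count from 622 to 120. Leaving out any other JEKO array also lowered it, to 208, 246 or 281, so most of the fall goes with the loss of an array, and what sets 120 apart from 208 was not decided. RNA quality stays open. The count with the beta-actin covariate was 785, but that covariate raised every count, and the count without the 3 arrays of lowest beta-actin value, which include this one, was 140. No biological explanation was tested.

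More genes were lower in HBL2 BR and higher in JEKO BR than independent lists would share (69 against 25.5). The shared estimate of spread did not account for this, since the ratio was 2.87 with each line fitted alone. Sorting genes into 3 classes of mean level did not remove the excess, since the ratio within them was 2.43. Level still varies within such wide classes, so a finer effect of mean level stays open. Power also depends on the spread of each gene, by which genes were not classed, so genes that are easier to call in both lines stay open. Nor is the excess particular to this direction. Within the same classes the ratio was 2.80 for genes higher in both lines, 1.67 for genes lower in both and 1.26 for genes higher in HBL2 and lower in JEKO. A biological opposition of the lines might remain, but genes are not independent and no test here separates it from shared regulation.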
